A study of Mus musculus with 16 samples.

How the data were processed

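RNA of CD19-positive splenic B cells from 16 mice, 4 per genotype group, had been extracted with Trizol, purified with phenol and chloroform, checked by Nanodrop and Bioanalyzer, biotin-labelled and hybridised to whole-transcript arrays, per the labels' protocols. The deposited values were log2 values per probe set that the authors had made with RMA, per the submitters' processing notes, which corrects background, normalizes between arrays and summarizes the probes of a set. The RMA version, software and settings are not given in the sources used here. The table held 35556 probe sets with values from 2.194 to 14.25 and 0 missing values, and the array medians of 6.32 to 6.41 are those of values on 1 common log2 scale. The values were used as deposited, with no further scaling in the main analysis. Because RMA normalizes between arrays, a change of all genes in 1 direction may be removed in part or whole, and differences of dim genes are compressed toward 0. The deposited values did not share 1 distribution. Their lower quartile was 4.904 to 5.002 in arrays with the TCL1 transgene and 4.99 to 5.148 in those without it. The median change in TCL1 Tg against NTg was -0.046, and -0.011 after quantile normalization.

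Probe sets were named through the platform annotation that came with the series. It lists 23410 of the probe sets, 21789 with 1 gene symbol and 1621 with several symbols, and 12146 are unnamed here. Of the probe sets with 1 symbol, 21698 matched a gene identifier of the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. The genome build of the array annotation is not given in the sources used here, so this table served for names and for the order of genes only, and no positions are printed. For the 999 genes with more than 1 probe set, the set with the highest mean over all arrays stood for the gene, which left 19938 genes for testing. Probe sets with several symbols or none were tested apart and no gene is named from them.

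Groups were taken from the sample titles. The labels call the samples biological replicates, so the spread between arrays includes that between animals. A linear model with 1 mean per group was fitted over the 16 arrays with limma, so that the 4 groups shared 1 estimate of the spread (12 residual degrees of freedom). The contrasts were tested with moderated statistics, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The contrasts were TCL1 Tg against NTg, PTPROt Tg against NTg, double Tg against TCL1 Tg, NTg and PTPROt Tg, and the interaction. The median standard error was 0.0969 for a difference between groups and 0.137 for the interaction.

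The 30 gene lists, the comparisons, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists held markers of B-1, follicular, marginal zone, germinal centre and plasma cells, G2/M and DNA replication genes, p53, NF-kB, FOXO and MYC targets, B cell receptor signalling, Wnt, interferon-stimulated and immediate-early genes, glycolysis, oxidative phosphorylation, apoptosis, homing, immunoglobulin constant regions, heat shock genes and lymphoid phosphatases. They also held markers of T, NK, macrophage, neutrophil, dendritic, erythroid, platelet and stromal cells. Each list was tested with camera of limma at its preset correlation of 0.01 between genes, adjusted over the 30 lists, and again with the correlation estimated from the residuals, under which 0 lists passed in any comparison. A list's difference with its SE is that of the per-array list means, 4 arrays against 4. Exact two-sided permutation tests of these means can go no lower than p = 0.0286 with 4 against 4.

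Named genes were the 10 that rose and the 10 that fell most in each comparison among genes past the threshold whose 4 values in one group all lay above the 4 of the other and whose higher group mean lay above the median of all gene means. For the interaction the numbers were 5 and 5. Antigen receptor segments, placeholder symbols and olfactory and vomeronasal receptors were passed over. Up to 4 members of smallest p were allowed per list where the list or a member passed, of which 3 were taken, and 12 genes were fixed whatever their p: Ptpro, Tcl1, Foxm1, Trp53, Cdkn1a, Cd5, Cd19, Syk, Zap70, Myc, Lef1 and Bcl2. Any other gene named is said to have been chosen after its values were seen.

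The relation of the PTPROt difference in TCL1-carrying arrays to the TCL1 difference was computed across genes with all TCL1 Tg arrays in both, with those arrays split 2 and 2 between the differences (6 assignments), and in 200 simulations of unchanged groups. The alternatives fixed in advance were quantile normalization, median centring of arrays, a filter that kept genes above the 40th percentile of gene means, the average of a gene's probe sets, and a trended and robust prior. Further ones were array weights, a fit of only the compared groups, the replicate number as a block, leaving out each array in turn, a 1.5-fold minimum, and the estimated correlation for lists. Added after the data were seen were an erythroid covariate, omission of the highest-erythroid array of each group, omission of the 200 measured genes on each side of H2-Ea, the exact permutation of list means, and a covariate for probe sets shared by several genes.

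The scripts' steps were tested on simulated data for double Tg against TCL1 Tg with 19938 genes. The noise was drawn independently for each gene and array, whereas genes of the real arrays vary together. At a log2 change of 0.5, 43 of 67 changed genes were recovered (64.2%), at 1 it was 62 of 67 (92.5%) and at 2 it was 66 of 66, and 16 of 19738 unchanged genes were called (0.0811%). In a simulation of TCL1 Tg against NTg over 19938 genes, a list shifted by 0.5 passed (1 of 1), as did 1 of the 28 lists that share no gene with it. R 4.3.3 with data.table (version 1.17.8) and limma 3.58.1 was used for the calculations, and Python 3.11.15 with matplotlib 3.10.9 for the plots. Raw scanner files were not used here, and detection of single probes above background was not analysed.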

Results

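Expression was measured in CD19-positive B lymphocytes isolated from the spleens of mice aged 4 months, with 1 single-channel Affymetrix whole-transcript array per sample. The 16 arrays fell into 4 groups of 4 samples that the labels call biological replicates: animals without a transgene (NTg), animals with the PTPROt transgene (PTPROt Tg), animals with the TCL1 transgene (TCL1 Tg) and animals with both (double Tg). PTPROt is the truncated form of a receptor-type protein tyrosine phosphatase made in lymphoid cells. TCL1 is a co-activator of the kinase AKT whose expression in mouse B cells leads to a disease like chronic lymphocytic leukaemia (CLL). The strain label was C3H/C57BL6 for every animal. The array medians lay between 6.32 and 6.41 on the log2 scale, correlations between any 2 arrays ranged from 0.964 to 0.993, and the number of arrays limited the precision, with a median standard error of 0.0969 for a difference between 2 groups. Group values are means of log2 values ± SD with n = 4 arrays, and differences are log2 fold changes ± SE from limma over the 16 arrays. The p-values are two-sided and adjusted over the 19938 genes tested (over the 30 lists for gene lists), and the number after a gene symbol at its first mention is its probe set. Detection above background was not tested. A difference whose lower group mean lay below every array median is marked as a lower bound, because differences of dim genes may be compressed. The median is not a detection limit, and the mark makes no allowance for sampling error or for choosing the largest differences.

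The probe set of mouse Ptpro (10542414) had mean values of 5.67 ± 0.25 in NTg, 5.91 ± 0.14 in PTPROt Tg, 5.52 ± 0.17 in TCL1 Tg and 5.53 ± 0.078 in double Tg arrays. Its difference between PTPROt Tg and NTg was 0.24 ± 0.11 (adjusted p = 1). Mouse Tcl1 (10402514) was at 4.46 ± 0.17 in NTg and 4.37 ± 0.28 in TCL1 Tg arrays, with a difference of -0.099 ± 0.12 (adjusted p = 0.618). Whether these probe sets match the transgenes' transcripts is not given in the sources used here, so they do not check the genotype labels. All animals were labelled female. In the 16 arrays the female-specific transcript Xist lay between 4.381 and 4.981, while the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 10.39 and 10.94, 9.383 and 9.978, and 9.235 and 9.726. These values contradict the sex label in all 16 arrays.

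The comparison of TCL1 Tg with NTg arrays addressed which genes differ in B cells that carry the TCL1 transgene at this age. Neto2 (10580382), an auxiliary subunit of kainate-type glutamate receptors, was higher in TCL1 Tg arrays, at 9.96 ± 0.20 against 5.31 ± 0.27, by at least 4.66 ± 0.12 on the log2 scale (adjusted p = 2.63e-13). H2-Ea (10450161), the alpha chain of the class II histocompatibility molecule I-E, decreased by at least 7.95 on the log2 scale ± 0.21, from 13.15 ± 0.19 to 5.21 ± 0.17 (adjusted p = 2.63e-13). The lower level of both genes lay below every array median, here and in the other TCL1 comparisons. Of measured list members, 41 of 51 G2/M genes, 24 of 45 DNA replication genes and 4 of 26 markers of B-1 cells, the B cell subset to which CLL-like cells in mice are related, rose, and 4 of 17 follicular B cell markers fell. Each of these lists passed camera at a preset correlation of 0.01 and had adjusted p = 0.140 with an estimated correlation. In all, 1005 genes passed the threshold of 0.05 on adjusted p, 619 of them higher and 386 lower in TCL1 Tg arrays. Of these, 120 changed at least 2-fold, 107 upward and 13 downward. The 4 arrays of one group all lay above the 4 of the other for 2389 genes (12% of those tested), where chance gives 2.86%.

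Besides Neto2, the largest increases among genes with separated groups were in Gnb3 (10547858), a G protein beta subunit, at 2.87 ± 0.70 (adjusted p = 0.0304), and in Fras1 (10523376), an extracellular matrix protein, at 2.57 ± 0.50 (adjusted p = 0.013). Cyp11a1 (10585794), the side-chain cleavage enzyme of steroid synthesis, rose by 2.20 ± 0.54 (adjusted p = 0.0313). The Ras-association family member Rassf6 (10531261) rose by 1.90 ± 0.33, the channel-like protein gene Tmc3 (10554667) by 1.83 ± 0.41 and Bhlhe41 (10549276), a transcription factor of B-1 cells, by 1.71 ± 0.36, with adjusted p between 0.00667 and 0.0227. Genes of cell division in this set were Top2a (10390707), a topoisomerase of dividing cells, at 1.88 ± 0.36 (adjusted p = 0.0114), and Cep55 (10462866), a midbody protein, at 1.62 ± 0.29 (adjusted p = 0.00876). Nek2 (10352767), a centrosomal kinase, rose by 1.56 ± 0.31 (adjusted p = 0.0147). Among genes that fell, Dnah8 (10443598), an axonemal dynein heavy chain, dropped from 9.29 ± 0.24 to 6.62 ± 0.077 (-2.67 ± 0.18, adjusted p = 3.36e-07). Msh5 (10450384), a meiotic MutS homolog, dropped from 8.28 ± 0.42 to 6.41 ± 0.029 (-1.87 ± 0.18, adjusted p = 8.18e-05). Both lie within 200 measured genes of H2-Ea in the gene order of the GRCm38.p6 assembly. The interferon-inducible genes Ifi206 (10360367) and Ifi213 (10360373) fell, at -1.22 and -1.12, as did the glyoxalase gene Glo1 (10471675) at -1.01 and Prg2 (10473399), which encodes the eosinophil major basic protein, at -0.99, with adjusted p between 0.00533 and 0.027. Pxdc1 (10408629), Pcp4 (10437205) and Cpne4 (10588380) were at -1.09, -1.03 and -0.97. Of the genes named for this comparison, Gnb3, Cyp11a1, Rassf6, Cep55, Ifi206, Prg2, Ttk (10587508), Chek1 (10592201), Nuggc (10416006), Gtse1 (10426016) and Zmat3 (10497673) also had a lower group mean below every array median, so their differences are lower bounds.

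**Figure D1:**
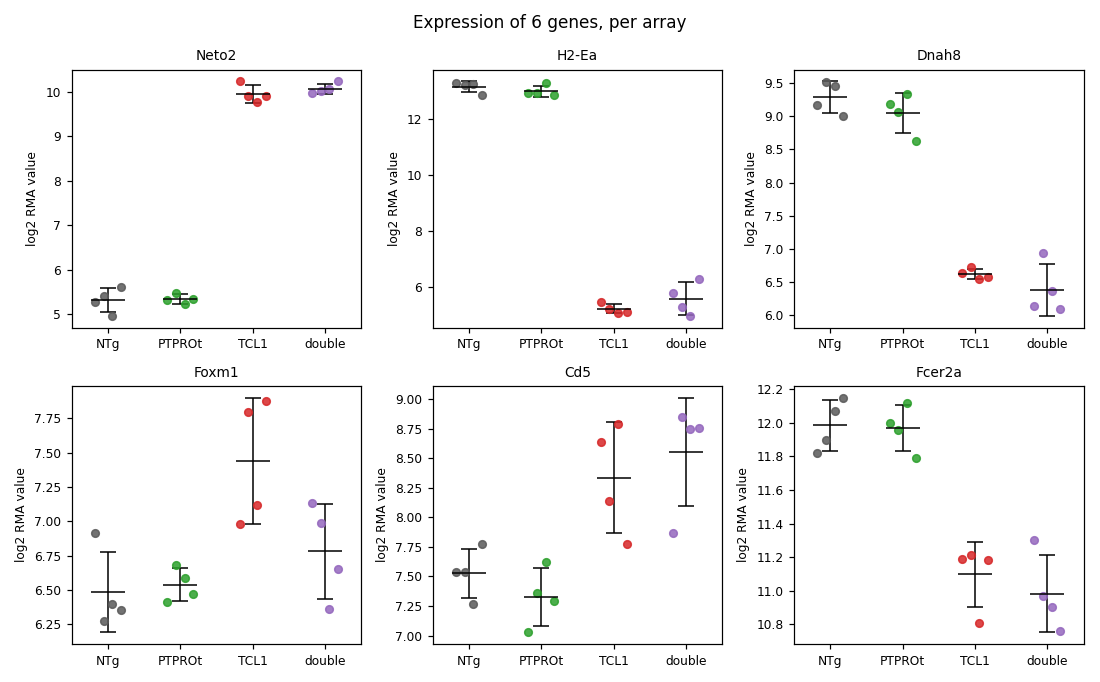
Log2 expression values (vertical axis) of Neto2, H2-Ea, Dnah8, Foxm1, Cd5 and Fcer2a in each of the 16 arrays, one point per array and one column per genotype group (horizontal axis), with the group mean and SD as bar and whiskers (n = 4). Neto2 averaged 9.96 in TCL1 Tg and 5.31 in NTg arrays, and H2-Ea averaged 5.21 and 13.15.

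Of 51 measured genes of the G2/M and FOXM1 target list, 41 rose, 0 fell and 10 did not pass (48 rose when adjusted over the list alone). Examples were Racgap1 (10432511), a regulator of cytokinesis, at 1.44 ± 0.20 (adjusted p = 0.00219), the spindle checkpoint kinase Ttk at 1.20 ± 0.19 (adjusted p = 0.00437) and the kinetochore protein gene Knstrn (10474825) at 0.93 ± 0.16 (adjusted p = 0.00667). Foxm1 (10542079), the transcription factor that drives this program, rose by 0.95 ± 0.21 (adjusted p = 0.0201). The list mean was 8.18 ± 0.49 in TCL1 Tg and 7.03 ± 0.55 in NTg arrays, a difference of 1.15 ± 0.37. It passed camera at the preset correlation of 0.01 (adjusted p = 4.38e-37) but not with the correlation estimated from the data (adjusted p = 0.140 with an estimated correlation). In the DNA replication and G1/S list, 24 of 45 measured members rose (40 adjusted over the list alone). Among them were the checkpoint kinase gene Chek1 at 1.10 ± 0.18, the clamp loader subunit Rfc5 (10533090) at 0.53 ± 0.098 and the helicase subunit Mcm6 (10357436) at 0.90 ± 0.17. Its mean differed by 0.69 ± 0.24 (adjusted p = 5.12e-27, and adjusted p = 0.140 with an estimated correlation). NTg replicate 1 had the highest value of its group for all 15 measured erythroid genes, with a median excess of 2.35, and its G2/M list mean was 7.84 against 6.64 to 6.86 in the other NTg arrays. The groups overlapped in both list means, as the lowest TCL1 Tg array was at 7.755 for G2/M. For DNA replication it was at 7.94, and the highest NTg array at 8.075. The exact permutation p of the list mean was 0.0857 for each list. With estimated correlations of 0.802 and 0.704, the members of a list are not independent.

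Among B cell subset lists, 4 of 26 measured B-1 and CLL-like markers rose, including Plscr1 (10587792) at 1.28 ± 0.32 and Arid3a (10364559) at 0.80 ± 0.20, and 20 rose when adjusted over the list alone. The list mean was 0.83 ± 0.21 higher, with all 26 differences above 0 (adjusted p = 4.15e-14, and adjusted p = 0.140 with an estimated correlation). Cd5 (10466040), the marker that defines CLL-like B cells, differed by 0.81 ± 0.23 and just missed the threshold (adjusted p = 0.0505). Follicular markers fell for 4 of 17 measured members (12 adjusted over the list alone), among them Fcer2a (10576757), the low-affinity IgE receptor CD23, at -0.89 ± 0.12 (adjusted p = 0.00144), Fchsd2 (10555438) at -0.44 and Zfp318 (10445531), a regulator of IgD splicing, at -0.55. The list mean differed by -0.39 ± 0.083 (adjusted p = 1.38e-06, and adjusted p = 0.140 with an estimated correlation). Germinal centre markers rose for 2 of 14 members, the DNA glycosylase gene Neil1 (10593887) at 1.54 ± 0.18 (adjusted p = 0.000378) and Nuggc at 1.28 ± 0.31, and for 8 adjusted over the list alone. The transcription factor gene Mybl1 (10353010) had a value of 2.45 ± 0.69 with adjusted p = 0.0508. The list mean differed by 0.96 ± 0.31 (adjusted p = 1.38e-06, and adjusted p = 0.140 with an estimated correlation). Of the 27 plasma cell and immunoglobulin secretion genes, 11 rose (18 adjusted over the list alone). They included the elongation factor gene Ell2 (10406254) at 0.61 ± 0.08 (adjusted p = 0.00117) and the protein disulfide isomerase genes Pdia4 (10544525) at 1.15 ± 0.17 and Txndc5 (10408741) at 0.87 ± 0.14. The mean difference was 0.48 ± 0.11 (adjusted p = 7.69e-16, and adjusted p = 0.138 with an estimated correlation).

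Growth and metabolic lists had smaller differences. Of 34 MYC target and ribosome biogenesis genes, 4 rose (13 adjusted over the list alone), among them the spermidine synthase gene Srm (10510391) at 0.53 and the ribosome biogenesis genes Nop58 (10346634) at 0.47 and Nip7 (10575144) at 0.36. Their mean difference was 0.24 ± 0.069 (adjusted p = 1.25e-10, and adjusted p = 0.140 with an estimated correlation). Myc (10424400) itself was at 0.39 ± 0.17 (adjusted p = 0.175). Oxidative phosphorylation genes rose for 3 of 36 members (14 adjusted over the list alone), Sdhb (10509858) at 0.38 and Atp5a1 (10456891) and Atp5c1 (10479996) at 0.23 and 0.24. The mean difference was 0.17 ± 0.057 (adjusted p = 1.75e-11, and adjusted p = 0.157 with an estimated correlation). Glycolysis genes rose for 5 of 20 members and fell for 1, in both countings, with the enzyme genes Tpi1 (10547830) at 0.71 and Pgam1 (10497321) at 0.38 and the glucose transporter gene Slc2a3 (10547641) at -0.58 as examples. The mean difference was 0.16 ± 0.073 (adjusted p = 0.0014, and adjusted p = 0.157 with an estimated correlation). The p53 target list had 3 risen and 1 fallen of 33 measured members (6 and 1 adjusted over the list alone). They were Gtse1, expressed in cycling cells and known to restrain p53, at 0.91, the apoptosome component Apaf1 (10371846) at 0.36, Zmat3 at 0.35 and Ier5 (10358978) at -0.33. The mean difference was 0.11 ± 0.025 (adjusted p = 0.00424, and adjusted p = 0.140 with an estimated correlation). Interferon-stimulated genes rose for 2 of 32 members in both countings, the peptide transporter gene Tap1 (10444244) at 0.44 and the nucleic acid sensor gene Zbp1 (10490150) at 0.46. Their mean difference was 0.11 ± 0.21 (adjusted p = 0.0202, and adjusted p = 0.749 with an estimated correlation). Single arrays moved this value. It was 0.19 and 0.20 without NTg replicates 1 and 2, and 0.20 and 0.18 without TCL1 Tg replicates 2 and 3. It did not pass without NTg replicates 3 and 4 (0.019 and 0.046) or without TCL1 Tg replicate 4, where the sign turned (-0.016, adjusted p = 0.593).

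**Figure D2:**
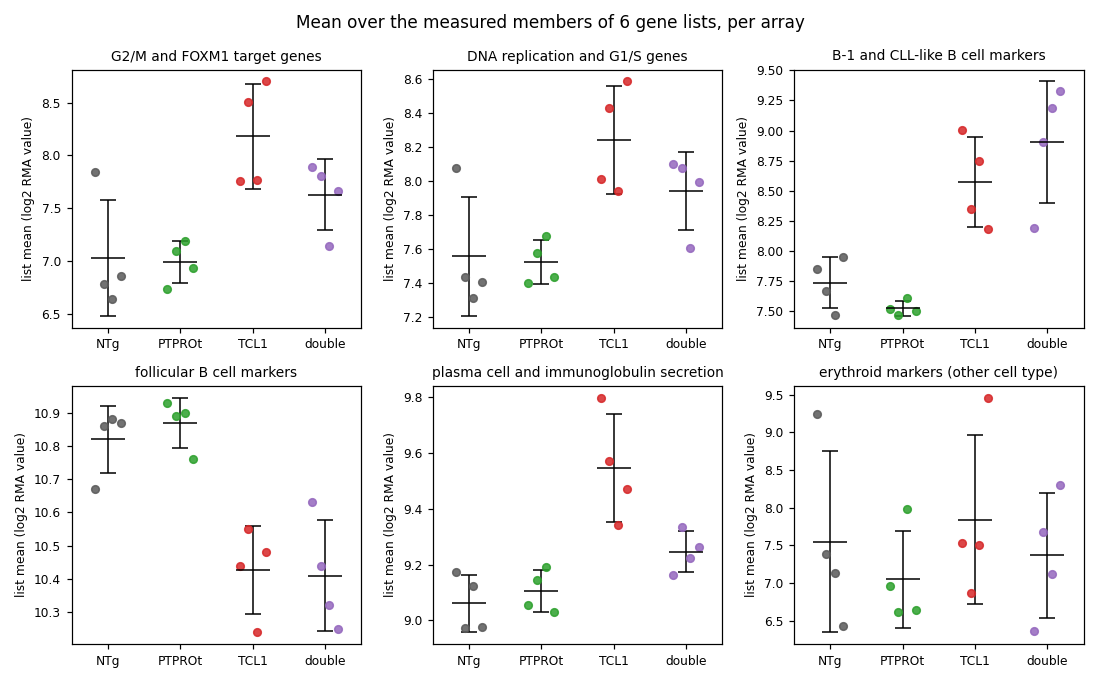
Mean log2 value over the measured members of 6 gene lists (vertical axis) in each of the 16 arrays, one point per array and one column per genotype group (horizontal axis), with the mean and SD of the 4 arrays as bar and whiskers. The G2/M list averaged 7.03 in NTg, 6.99 in PTPROt Tg, 8.18 in TCL1 Tg and 7.63 in double Tg arrays, and the erythroid list ranged from 6.43 to 9.24 within NTg.

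Markers of other cell types were measured beside these groups. The macrophage list averaged 9.073 in NTg and 8.822 in TCL1 Tg arrays, above the upper quartile of every array (8.053 to 8.212). The erythroid list reached 9.243 in an NTg and 9.462 in a TCL1 Tg array. The T, NK, neutrophil, dendritic, platelet and stromal lists averaged between 5.595 and 6.772 in NTg arrays. The share of RNA from other cells was not measured, so a difference need not be a change within B cells. T cell markers rose for 4 of 23 members (7 adjusted over the list alone), including Cd27 (10547985), a receptor that activated B cells also carry, at 0.96, the cytokine receptor gene Il2rb (10430344) at 0.92 and the CD3 subunit gene Cd3g (10593015) at 1.15. Their mean difference was 0.37 ± 0.19 (adjusted p = 1.21e-07, and adjusted p = 0.317 with an estimated correlation). Natural killer (NK) cell markers rose for 2 of 17 members in both countings, Tbx21 (10390328), a transcription factor also made in some activated B cells, at 0.88 and Il2rb. Their mean difference was 0.28 ± 0.27 (adjusted p = 0.0124, and adjusted p = 0.668 with an estimated correlation). Macrophage markers fell for 1 of 23 members, the receptor kinase gene Mertk (10475890) at -0.60, and for 2 adjusted over the list alone. Their mean difference was -0.25 ± 0.14 (adjusted p = 0.00636, and adjusted p = 0.668 with an estimated correlation). Without TCL1 Tg replicate 3 the T cell difference was 0.22 and the NK cell difference 0.019 (adjusted p = 0.919). The macrophage difference did not pass without NTg replicate 1 (-0.16, adjusted p = 0.256) or TCL1 Tg replicate 2 (-0.18, adjusted p = 0.0679). The mean difference of the erythroid list was 0.29 ± 0.82 (adjusted p = 0.181), of neutrophil markers 0.12 (adjusted p = 0.429), and of dendritic cell markers 0.0081 (adjusted p = 0.980). Platelet markers differed by -0.016 (adjusted p = 0.980) and stromal markers by -0.11 (adjusted p = 0.124).

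The remaining lists did not pass camera. Mean differences were -0.092 for marginal zone B cell markers (adjusted p = 0.890), -0.044 for B cell receptor signalling (adjusted p = 0.890), and 0.12 for NF-kB targets (adjusted p = 0.718). They were -0.044 for FOXO targets (adjusted p = 0.850), 0.12 for the Wnt pathway (adjusted p = 0.199) and -0.15 for immediate-early genes (adjusted p = 0.199). The values were 0.048 for apoptosis regulators (adjusted p = 0.367) and 0.055 for B cell homing (adjusted p = 0.429). Further values were -0.24 for the 3 measured immunoglobulin constant regions (adjusted p = 0.695), 0.078 for heat shock genes (adjusted p = 0.181) and -0.026 for lymphoid phosphatases (adjusted p = 0.695). The median of the apoptosis and dendritic cell lists (-0.046 and -0.088) had the opposite sign to the mean, and camera placed the platelet and phosphatase lists upward against a negative mean and median. For every list that passed in this comparison, mean, median and test had 1 sign. Single members still changed in these lists. The costimulatory receptor gene Cd40 (10478678) fell, at -0.62, as did the pro-apoptotic gene Bmf (10486112) at -0.52 and the ERK phosphatase gene Dusp6 (10366043) at -0.75. Akt1 (10402766) rose by 0.33, the Wnt receptor gene Ryk (10588243) by 1.09 and the integrin gene Itgb1 (10576661) by 1.06. Syk (10405216), Zap70 (10345509), Lef1 (10496091) and Bcl2 (10357043) did not pass, at 0.11, 0.36, 0.15 and -0.14. Trp53 and Cd19 had no probe set of their own, and Cdkn1a only one shared with another symbol.

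Dim genes leaned downward: 216 of the 386 lower calls and 22 of the 619 higher calls lay in the dimmer 40% of genes. The mean over 1027 olfactory receptor genes, which B cells hardly express, was 4.30 ± 0.089 in TCL1 Tg and 4.55 ± 0.16 in NTg arrays (exact permutation p = 0.0571). The count of changed genes varied with the arrays kept: it was 1972 without NTg replicate 1, 405, 163 and 359 without NTg replicates 2, 3 and 4, and 472, 547 and 400 without TCL1 Tg replicates 1, 2 and 4. It was 2094 with array weights (1109 higher, 985 lower), 140 when only these 8 arrays were fitted, and 88 with the mean of dim probe sets shared by 6 or more genes as a covariate, a setting added after the data were seen. The excess of higher calls varied too: 41 were higher and 47 lower with that covariate, and 729 higher and 222 lower with a filter on dim genes.

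The comparison of PTPROt Tg with NTg arrays addressed the effect of the phosphatase transgene alone. In limma, 0 genes passed the threshold, the smallest adjusted p was 0.981, and 362 genes had an unadjusted p under 0.05 where chance gives 997. The count stayed at 0 under every other setting run with all arrays of both groups, and without the array of highest erythroid mean in each group. The groups were separated for 240 genes (1.2%, against 2.86% by chance). Among the genes fixed in advance, Foxm1 differed by 0.052 ± 0.21, Cd5 by -0.20 ± 0.23, Myc by -0.16 ± 0.17 and Bcl2 by 0.046 ± 0.11, all with adjusted p = 1.

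Although no single gene passed, 4 lists passed camera. B-1 and CLL-like markers were lower for 21 of 26 members (mean -0.21 ± 0.11, adjusted p = 0.000578), for example the costimulatory ligand gene Cd80 (10435704) at -0.55 and Bhlhe41 at -0.66, each with adjusted p = 1. Macrophage markers were lower for 19 of 23 members (mean -0.14, adjusted p = 0.000227), for example Spic (10371662), a transcription factor of red pulp macrophages, at -0.38 and Axl (10561104) at -0.23. FOXO targets were higher for 20 of 25 members (mean 0.11, adjusted p = 0.0295), for example Ccng2 (10523297) at 0.15 and Irs2 (10576971) at 0.16. Erythroid markers were lower for 15 of 15 members (mean -0.50 ± 0.68, adjusted p = 0.000623), for example the carbonic anhydrase gene Car2 (10490923) at -0.78 and the erythropoietin receptor gene Epor (10591660) at -0.37. In each of these lists 0 members changed, over all genes or adjusted over the list alone, and none of the lists passed with an estimated correlation (adjusted p = 0.969 with an estimated correlation for all 4). Of the 4 list calls, 3 held with the filter on dim genes and 3 without the highest-erythroid arrays. With the erythroid covariate 2 of 3 held. Single arrays moved each of these means. Without NTg replicate 1 the erythroid mean difference was 0.064 (adjusted p = 0.717) and 8 lists passed, and without NTg replicate 2 there were 7. The erythroid value was -0.87 without NTg replicate 4, -0.81 without PTPROt Tg replicate 3 and -0.37 without PTPROt Tg replicate 4 (adjusted p = 0.0978). Macrophage markers were at -0.045 without NTg replicate 1 (adjusted p = 0.342) and at -0.095 without PTPROt Tg replicate 4 (adjusted p = 0.0971). They were at -0.23 without NTg replicate 4 or PTPROt Tg replicate 3. B-1 markers were at -0.14 without NTg replicate 4. FOXO targets passed without NTg replicate 2 (0.17) or PTPROt Tg replicate 4, but not without any other single array of these groups (adjusted p between 0.0705 and 0.192), with a mean of 0.058 without NTg replicate 1.

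Leaving out NTg replicate 3 gave 5 genes, chosen here after their values were seen: Apobec3 (10425321), an antiviral cytidine deaminase gene, at -2.80, D730005E14Rik at -2.94, Cbx7 at -1.19, Ly6e at -0.72 and Lynx1 at -1.63. The value of D730005E14Rik is a lower bound in size, as its lower level of 5.85 lay below every array median. Leaving out PTPROt Tg replicate 2 gave 1, the amino acid transporter gene Slc1a5 at -1.54 (over all arrays -1.20). Apobec3 lay between 10.77 and 11.03 in 3 NTg arrays, at 8.27 in NTg replicate 3 and at 8.09 ± 0.33 in PTPROt Tg arrays.

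The comparison of double Tg with TCL1 Tg arrays addressed how the phosphatase alters B cells that carry TCL1. Here too 0 genes passed the threshold in limma (729 at an unadjusted p under 0.05, where chance gives 997), and 409 genes had separated groups (2.05%, against 2.86% by chance). Cell-cycle genes had lower means in double Tg arrays. All 51 G2/M and FOXM1 targets had differences below 0, with a mean of -0.55 ± 0.30 (adjusted p = 3.73e-30, and adjusted p = 0.353 with an estimated correlation). So had 43 of 45 DNA replication genes, with a mean of -0.30 ± 0.19 (adjusted p = 4.96e-16, and adjusted p = 0.428 with an estimated correlation). Foxm1 was at 6.78 ± 0.35 in double Tg and 7.44 ± 0.46 in TCL1 Tg arrays, a difference of -0.66 ± 0.21 (adjusted p = 1). Plasma cell genes were lower for 25 of 27 members, with a mean of -0.30 ± 0.10 (adjusted p = 3.06e-17, and adjusted p = 0.0997 with an estimated correlation) and 8 members that fell when adjusted over the list alone. B-1 and CLL-like markers were higher for 24 of 26 members, with a mean of 0.33 ± 0.31 (adjusted p = 2.19e-06, and adjusted p = 0.443 with an estimated correlation). Without TCL1 Tg replicate 4 the DNA replication and B-1 differences were -0.18 and 0.20. The DNA replication difference was -0.19 without double Tg replicate 3. The B-1 difference was 0.57 without double Tg replicate 1 and 0.19 without double Tg replicate 4.

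The exact permutation p of the list mean, 4 arrays against 4, was 0.2 for G2/M, 0.257 for DNA replication and 0.0286 for plasma cell genes, the smallest that 4 against 4 allows. None of the 30 lists passed after adjustment of these values, which a list at this floor could do only along with many others. Examples of the G2/M list were the phosphatase gene Cdc25c (10458195) at -0.77 ± 0.19 (adjusted p = 0.916) and Knstrn at -0.57 ± 0.16 (adjusted p = 1). Of the plasma cell list, Ell2 was at -0.40 ± 0.08 (adjusted p = 0.44), Txndc5 at -0.60 ± 0.14 (adjusted p = 0.73) and the immunoglobulin joining chain gene Jchain (10531126) at -1.01 ± 0.28 (adjusted p = 1). Of the B-1 list, the calcium-binding protein gene S100a6 (10493820) was at 0.88 ± 0.39 (adjusted p = 1) and the transcription factor gene Zbtb32 (10562044) at 1.00 ± 0.45 (adjusted p = 1). Germinal centre markers were lower for 13 of 14 members (mean -0.37 ± 0.38, adjusted p = 5.45e-05), with 1 past the threshold adjusted over the list alone, and Neil1 was at -0.68. Interferon-stimulated genes were lower for 28 of 32 (mean -0.15, adjusted p = 0.000152) and p53 targets for 24 of 33 (mean -0.063, adjusted p = 0.00399). MYC targets were higher for 31 of 34 (mean 0.074, adjusted p = 0.000152) and immediate-early genes for 22 of 34 (mean 0.068, adjusted p = 0.041), for example Bop1 (10429908) at 0.25 and Nr4a1 (10427035) at 0.65. With an estimated correlation these 5 lists had adjusted p = 0.353, 0.490, 0.197, 0.489 and 0.490, in the order given. Of all 13 list calls in this comparison, 12 held with the replicate block and 9 without the highest-erythroid arrays. With the erythroid covariate 9 of 12 held. The germinal centre difference was -0.17 without TCL1 Tg replicate 2, -0.61 without TCL1 Tg replicate 3 and -0.19 without double Tg replicate 3. The interferon difference was -0.24 without TCL1 Tg replicate 2 and -0.022 without TCL1 Tg replicate 4 (adjusted p = 0.646). MYC targets were at 0.039 without double Tg replicate 4 (adjusted p = 0.0812). Immediate-early genes were at 0.12 without TCL1 Tg replicate 3. They did not pass without TCL1 Tg replicates 1, 2 or 4 or double Tg replicates 1 or 4 (0.036 to 0.068, adjusted p between 0.0868 and 0.217). Cd5 differed by 0.22 ± 0.23 and Myc by 0.35 ± 0.17, both with adjusted p = 1.

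Markers of some other cell types also had lower means. T cell markers were lower for 21 of 23 members (mean -0.19), NK cell markers for 16 of 17 (mean -0.30), dendritic cell markers for 13 of 16 (mean -0.097) and erythroid markers for 15 of 15 (mean -0.48 ± 0.70). The adjusted p were 1.54e-05, 1.54e-05, 0.0182 and 0.00594, and 0.490, 0.432, 0.365 and 0.572 with an estimated correlation. Examples were Icos (10346799) at -0.30, Prf1 (10363475) at -0.37, Clec9a (10542181) at -0.38 and Gata1 (10603417) at -0.62. Macrophage, stromal, neutrophil and platelet markers did not pass camera, with means of -0.00645, 0.00113, -0.126 and -0.0648 (adjusted p = 0.992, 0.992, 0.0578 and 0.287). Without TCL1 Tg replicate 3 the T cell, NK cell and dendritic cell differences were -0.033, -0.036 and -0.074 (adjusted p = 0.347, 0.610 and 0.159). Without double Tg replicate 1 the T cell, dendritic cell and erythroid differences were -0.097, -0.063 and -0.14 (adjusted p = 0.113, 0.198 and 0.496). Without TCL1 Tg replicate 4 the erythroid mean difference was 0.063 (adjusted p = 0.646) and the T cell difference -0.30. The erythroid difference was -0.80 without TCL1 Tg replicate 2 and -0.79 without double Tg replicate 4. The count of genes stayed at 0 under every other setting run with all arrays of both groups and without the highest-erythroid array of each group. Only 1 gene, Gm5486 at 2.09 (1.53 over all arrays), chosen after its value was seen, passed without double Tg replicate 1. The smallest adjusted p was 0.378, for the calcium channel gene Cacna1h (10448925) at -0.62 ± 0.10, also chosen after its value was seen. In simulated data for this comparison, with noise independent between genes and arrays, a log2 change of 1 was recovered for 62 of 67 genes. Genes of the real arrays varied together, so this share is not the power of the real comparison. Gm5486, at 1.53 over all arrays, did not pass there.

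The interaction contrast tested whether the PTPROt difference itself differed between arrays with and without TCL1. It gave 0 genes in limma (559 at an unadjusted p under 0.05, where chance gives 997), the smallest adjusted p was 0.851, and 12 lists passed camera. The mean interaction was 0.54 for B-1 and CLL-like markers (adjusted p = 2.16e-09), -0.51 for G2/M genes, with 49 of 51 below 0 (adjusted p = 1.44e-13), and -0.34 for plasma cell genes, with 27 of 27 below 0 (adjusted p = 3.69e-13). With an estimated correlation these had adjusted p = 0.519, 0.599 and 0.238, and none of the 12 lists passed. The G2/M value was -0.78 without NTg replicate 1 and -0.34 without TCL1 Tg replicate 4. Foxm1 had an interaction of -0.71 ± 0.29, Cd5 of 0.42 ± 0.32 and Myc of 0.51 ± 0.24, each with adjusted p = 1. Without NTg replicate 3 the count was 4 (Apobec3, D730005E14Rik, Cbx7 and Ly6e, between 0.79 and 3.06), and without PTPROt Tg replicate 2 it was 1 (Slc1a5 at 1.60). These genes were chosen after their values were seen.

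The comparison of double Tg with NTg arrays addressed the combined effect of the transgenes. Neto2 was higher by at least 4.77 ± 0.12 (adjusted p = 3.24e-13) and H2-Ea fell by at least 7.59 on the log2 scale ± 0.21, with Dnah8 at -2.91 ± 0.18 and Msh5 at -2.06 ± 0.18. In all, 986 genes passed the threshold, 617 higher and 369 lower, of which 96 changed at least 2-fold (83 and 13), and 2847 genes had separated groups (14.3%, against 2.86% by chance). Cyp11a1 rose by 2.84 ± 0.54 (adjusted p = 0.00999), Gnb3 by 2.87 ± 0.70, Fras1 by 2.75 ± 0.50, Tmc3 by 2.04 ± 0.41 and Rassf6 by 2.07 ± 0.33. The keratin gene Krt8 (10432918) rose by 2.32 ± 0.54 (adjusted p = 0.0229), and S100a6 by 2.23 ± 0.39 (adjusted p = 0.00685). Zbtb32 rose by 2.20 ± 0.45 (adjusted p = 0.013) and Robo1 (10436519), an axon guidance receptor gene, by 1.98 ± 0.45 (adjusted p = 0.0217). Fcer2a fell by 1.00 on the log2 scale ± 0.12 (adjusted p = 0.000668), with Il12a (10492540), a subunit of the cytokine IL-12, at -1.12 ± 0.18 (adjusted p = 0.00515) and Cd93 (10488382) at -1.03 ± 0.24 (adjusted p = 0.0239). The linker histone gene H1f2 (10404059) fell by 1.00 on the log2 scale, with Pcp4 at -1.35, Pxdc1 at -1.10 and Prg2 at -0.99. The differences of Msh5, Cyp11a1, Gnb3, Rassf6, S100a6, Robo1, Prg2 and Ttk are lower bounds too, with a lower group mean below every array median. Cd5 rose by 1.03 ± 0.23 (adjusted p = 0.0188) and Myc by 0.74 ± 0.17 (adjusted p = 0.0234), while Foxm1 was at 0.30 ± 0.21 (adjusted p = 0.386).

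B-1 and CLL-like markers rose for 17 of 26 members (24 adjusted over the list alone) with a mean of 1.17 ± 0.27 (adjusted p = 2.88e-21, and adjusted p = 0.141 with an estimated correlation). Plscr1 was at 1.77 and the structural protein gene Ahnak (10461369) at 1.55. Follicular markers fell for 7 of 17 (9 adjusted over the list alone), with a mean of -0.41 ± 0.097 (adjusted p = 6.54e-06, and adjusted p = 0.255 with an estimated correlation), among them Fchsd2 at -0.60 and Zfp318 at -0.64. MYC targets rose for 11 of 34 (18 adjusted over the list alone; mean 0.31 ± 0.078, adjusted p = 1.63e-16, and adjusted p = 0.141 with an estimated correlation), among them Mybbp1a (10378088) at 0.35 and Srm at 0.66. Cell-cycle lists had few single members past the threshold: 2 of 51 G2/M genes rose in both countings (Racgap1 at 1.26 and Ttk at 0.84; list mean 0.60 ± 0.32) and 3 of 45 DNA replication genes (4 adjusted over the list alone; mean 0.39 ± 0.21). The lists had adjusted p = 2.24e-14 and 1.07e-12, and adjusted p = 0.466 with an estimated correlation for both. Oxidative phosphorylation genes rose for 6 of 36 (18 adjusted over the list alone; mean 0.20, adjusted p = 8.59e-14, and 0.255 with an estimated correlation). Glycolysis genes rose for 6 and fell for 1 of 20 (10 and 2 adjusted over the list alone; mean 0.21, adjusted p = 6.66e-05, and 0.195 with an estimated correlation), with Tpi1 at 0.81. Germinal centre markers rose for 1 of 14 (Neil1 at 0.86) and plasma cell genes for 3 of 27 (4 adjusted over the list alone; Pdia4 at 1.07). Their means were 0.59 and 0.19, with adjusted p = 0.00592 and 0.000169 (0.466 for both with an estimated correlation). T cell markers rose for 1 of 23 (Cd27 at 0.73; mean 0.19 ± 0.12, adjusted p = 0.00437, and 0.648 with an estimated correlation). Macrophage markers fell for 1 of 23 (Mertk at -0.68; 6 adjusted over the list alone; mean -0.26 ± 0.17, adjusted p = 0.00747, and 0.648 with an estimated correlation). Neither passed without NTg replicate 1 (0.13 and -0.17, adjusted p = 0.0554 and 0.317). T cell markers did not pass without double Tg replicate 3 (0.12, adjusted p = 0.0744), nor macrophage markers without double Tg replicate 1 (-0.18, adjusted p = 0.183).

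Of the lower calls, 160 lay in the dimmer 40% of genes, against 13 of the higher. The count was 1773, 538, 251 and 528 without NTg replicates 1 to 4 and 573, 449 and 270 without double Tg replicates 2, 3 and 4. It was 1989 with array weights (1068 higher, 921 lower), 416 when only these 8 arrays were fitted, and, in settings added after the data were seen, 2126 with an erythroid covariate (1084 higher, 1042 lower), 471 without the highest-erythroid array of each group and 112 with the shared probe set covariate. With the last of these the majority turned, to 42 higher and 70 lower, while median centring gave 626 higher and 245 lower.

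The comparison of double Tg with PTPROt Tg arrays addressed the effect of TCL1 where the phosphatase was present. Neto2 was higher by at least 4.74 ± 0.12 (adjusted p = 3.61e-13), and H2-Ea, Dnah8 and Msh5 fell, at -7.43 ± 0.21, -2.68 ± 0.18 and -1.83 ± 0.18. A total of 1227 genes passed the threshold, 707 higher and 520 lower, of which 147 changed at least 2-fold (124 and 23), and 3144 genes had separated groups (15.8%, against 2.86% by chance). Cyp11a1 rose by 3.64 ± 0.54 (adjusted p = 0.00185), Fras1 by 3.25 ± 0.50, Gnb3 by 2.98 ± 0.70 and Tmc3 by 2.91 ± 0.41. Adm (10556297), the gene of the peptide hormone adrenomedullin, rose by 3.06 ± 0.61 (adjusted p = 0.00988), and the cytoskeletal adaptor gene Pstpip2 (10456904) by 3.04 ± 0.58 (adjusted p = 0.00781). Zbtb32 rose by 2.88 ± 0.45 (adjusted p = 0.00218) and Bhlhe41 by 2.51 ± 0.36 (adjusted p = 0.00167). Apobec3 rose by 3.54 ± 0.42 (adjusted p = 0.000529), from 8.09 ± 0.33 to 11.63 ± 0.087, with NTg replicate 3, at 8.27, on the level of the PTPROt Tg arrays. The complement receptor gene Cr2 (10361292) fell (-1.20 ± 0.33, adjusted p = 0.0409), and so did the glycosyltransferase gene Gcnt1 (10466521) at -1.19, Pcp4 at -1.74, Prg2 at -1.17, Pxdc1 at -1.15 and Ifi213 at -1.14. The differences of H2-Ea, Msh5, Cyp11a1, Fras1, Gnb3, Tmc3, Adm and Prg2 are lower bounds, with a lower group mean below every array median. The nucleoside diphosphate kinase family gene Nme7 (10351277) was at -1.93 ± 0.50 (adjusted p = 0.0327), with 1 double Tg array at 9.57 against a group mean of 8.23 ± 0.89. Cd5 rose by 1.23 ± 0.23 (adjusted p = 0.00668) and Myc by 0.90 ± 0.17 (adjusted p = 0.00792), while Foxm1 was at 0.24 ± 0.21 (adjusted p = 0.471).

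B-1 and CLL-like markers rose for 21 of 26 members (24 adjusted over the list alone) with a mean of 1.38 ± 0.25 (adjusted p = 3.15e-26, and adjusted p = 0.133 with an estimated correlation). The galectin gene Lgals1 (10425161) was at 2.06 and Plscr1 at 2.15. Follicular markers fell for 8 of 17 (11 adjusted over the list alone; mean -0.46 ± 0.092, adjusted p = 4.68e-07, and 0.244 with an estimated correlation), among them Fcer2a at -0.98 and Zfp318 at -0.74. MYC targets rose for 13 of 34 (20 adjusted over the list alone; mean 0.32 ± 0.060, adjusted p = 7.65e-17, and 0.133 with an estimated correlation), Srm by 0.75 and Pa2g4 (10373454) by 0.62. Oxidative phosphorylation genes rose for 8 of 36 (17 adjusted over the list alone; mean 0.19, adjusted p = 6.13e-13, and 0.244 with an estimated correlation). G2/M genes rose for 2 of 51 in both countings (Racgap1 at 1.21; mean 0.64 ± 0.20, adjusted p = 7.65e-17, and 0.467 with an estimated correlation). DNA replication genes rose for 5 of 45 (10 adjusted over the list alone), with the cyclin gene Ccne1 (10562563) at 0.83 (mean 0.42 ± 0.13, adjusted p = 4.81e-14, and 0.467 with an estimated correlation). Glycolysis genes rose for 6 and fell for 2 of 20 (7 and 2 adjusted over the list alone; mean 0.19, adjusted p = 0.000657, and 0.244 with an estimated correlation). Plasma cell genes rose for 4 of 27 in both countings, with Creld2 (10426098) at 0.71 (mean 0.14, adjusted p = 0.0025, and 0.545 with an estimated correlation). Germinal centre markers rose for 1 of 14 (mean 0.39, adjusted p = 0.0415, and 0.644 with an estimated correlation). FOXO targets fell for 2 of 25 in both countings, with Btg1 (10365971) at -0.41 (mean -0.20, adjusted p = 0.0266, and 0.483 with an estimated correlation). Germinal centre markers did not pass without PTPROt Tg replicates 1 or 3 or double Tg replicates 1 or 2 (adjusted p between 0.0881 and 0.191), with a mean of 0.21 without double Tg replicate 1. FOXO targets did not pass without PTPROt Tg replicates 1 or 3 or double Tg replicate 3 (adjusted p between 0.0516 and 0.0786). Of the lower calls, 188 lay in the dimmer 40% of genes, against 26 of the higher, and the olfactory receptor genes averaged 4.33 ± 0.05 in double Tg and 4.53 ± 0.15 in PTPROt Tg arrays (exact permutation p = 0.0571). The count was 504, 629 and 635 without PTPROt Tg replicates 1, 2 and 4, and 747, 514 and 392 without double Tg replicates 2, 3 and 4. It was 2919 with array weights and, in settings added after the data were seen, 457 without the highest-erythroid arrays and 108 with the shared probe set covariate. The majority turned with array weights (1374 higher, 1545 lower) and with the shared probe set covariate (51 higher, 57 lower), while median centring gave 733 higher and 326 lower.

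The TCL1 comparisons with and without PTPROt, which share no array, had a correlation of 0.788 across genes, which are not independent replicates. Of the genes higher in both, 272 passed in each (21.9 for independent lists), of the genes lower in both 137 did (10.1 for independent lists), and 0 passed in opposite directions. Of the 1005 genes called in TCL1 Tg against NTg, 989 had the same sign in double Tg against PTPROt Tg, Neto2 and H2-Ea among them. Whether PTPROt moved the TCL1 changes back was read from the correlation across genes of double Tg minus TCL1 Tg with TCL1 Tg minus NTg. It was -0.302 (covariance -0.0101) with the TCL1 Tg arrays in both differences, where simulated unchanged groups gave -0.5 (covariance -0.00881), and 0.00753 on average (-0.108 to 0.119 over 6 assignments; covariance 7e-04) when the TCL1 Tg arrays were split between the differences.

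**Figure D3:**
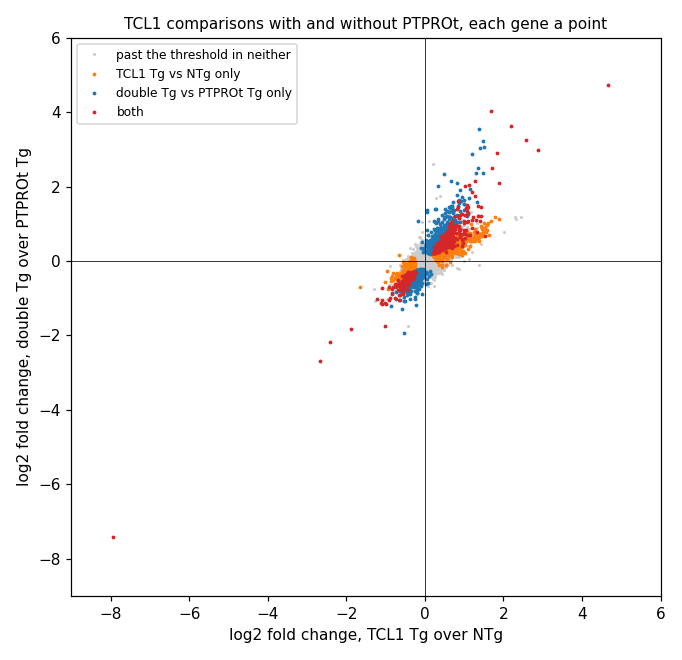
Log2 fold change of each of the 19938 genes in TCL1 Tg over NTg (horizontal axis) and in double Tg over PTPROt Tg (vertical axis), one point per gene, coloured by the comparison in which it passed the threshold of 0.05 on adjusted p. Neto2 lies at 4.66 and 4.74, H2-Ea at -7.95 and -7.43, and 409 genes passed in both.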

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

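The tests of the genes next to H2-Ea, of a mislabelled sample, of a direct effect on H2-Ea, of the spread of the cell-cycle means, of dim single-gene probe sets and of lower transcription were chosen only after the results they bear on had been seen. The settings with an erythroid or a shared probe set covariate were added after the data had been seen.

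H2-Ea lay between 12.84 and 13.29 in the 8 arrays without the TCL1 transgene and between 4.954 and 6.286 in the 8 with it, and Dnah8 and Msh5, within 200 measured genes of it, followed the transgene too. Lower transcription of the class II genes in general is argued against by the other 8 class II genes measured, whose median change was 0.0864 (-0.25 to 0.383, 0 past the threshold). A linked strain haplotype is a candidate explanation that the values leave open, since C57BL/6 animals carry an H2-Ea gene that is not expressed and C3H animals an expressed one: 14 of the 400 surrounding genes passed in both TCL1 comparisons, against a mean of 8.22 in 10000 shifted windows (permutation p = 0.0673). Of the other 3 genes with separate levels that follow the transgene, 2 lay in this window, Dnah8 and Msh5, whose places prompted the test and so decide nothing. A direct effect of the TCL1 transgene on H2-Ea cannot be told apart from a linked haplotype by the H2-Ea levels, because either would give the gap of 6.56. Such an effect on H2-Ea alone would leave the differences of Dnah8 and Msh5 unaccounted for. The strain origin of each animal is not given in the sources used here, so genes of the TCL1 comparisons may include linked strain differences. Without genes near H2-Ea, 970, 939 and 1191 genes passed in TCL1 Tg against NTg, double Tg against NTg and double Tg against PTPROt Tg. A mislabelled sample cannot be told apart by H2-Ea either: 0 arrays had a value nearer to the other TCL1 status, which follows from the choice of a gene that goes with the labels.

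The cell-cycle lists had lower means in double Tg than in TCL1 Tg arrays, with differences of -0.552 ± 0.30 for G2/M and -0.298 ± 0.19 for DNA replication genes. The latter was -0.183 without TCL1 Tg replicate 4 and -0.185 without double Tg replicate 3. No explanation tried is argued against by the tables. With the erythroid mean of each array as a covariate the differences were -0.439 ± 0.26 and -0.218, and with the germinal centre mean -0.297 ± 0.24 and -0.14, so that neither cell type can be told apart from an effect on dividing cells with these errors. The spread between arrays of a group may also account for the pattern, with an exact permutation p of 0.2 for the G2/M mean. An effect of PTPROt on cell division in TCL1-carrying B cells stays open.

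Among dim probe sets shared by several genes (mean below 8 on the log2 scale), medians were lower with the TCL1 transgene, the more so the more genes shared them. The median change in TCL1 Tg against NTg was -0.138 for 264 sets of 2 genes, -0.331 for 164 sets of 3 to 5 and -0.647 for sets of 6 or more (95 of them below 0). Probe sets are not replicates. By array, the sets of 6 or more averaged 5.43 ± 0.37 in TCL1 Tg and 6.21 ± 0.48 in NTg (exact permutation p = 0.0571). They averaged 5.46 ± 0.13 in double Tg and 6.17 ± 0.3 in PTPROt Tg arrays (exact permutation p = 0.0286). The authors' normalization of dim values is argued against as the whole source by 4405 single-gene probe sets of the same level, whose median was -0.0964. Genomic DNA in the labelled RNA is a candidate source, since it would add signal in proportion to the copies in the genome. Its test was written before its result was seen, but for a pattern added after the data were seen. The difference between the sets of 6 or more and of 2 genes was -0.509. That value restates the medians above, so it lends this source no support beyond the pattern itself. Lower transcription with the TCL1 transgene cannot be told apart from genomic DNA, because less transcription and less genomic DNA would both give lower values. The array means of the sets of 6 or more genes overlapped between arrays with and without the transgene. The gap was -0.275 between the lowest array without (5.70) and the highest with the transgene (5.98). With this level as a covariate 88, 112 and 108 genes passed in TCL1 Tg against NTg, double Tg against NTg and double Tg against PTPROt Tg, and as the covariate differs between the groups it also takes up part of any group difference.

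Other splits of the same arrays were counted for each comparison. For TCL1 Tg against NTg and double Tg against NTg, 1 of 35 splits, the real one, gave as many genes as the 1005 and 986 observed. The same held for the 1227 genes of double Tg against PTPROt Tg. These shares are the smallest that 35 splits allow, and the comparisons share arrays. They argue against a random grouping but cannot exclude it. The highest other counts were 890, 49 and 0. The split with 890 genes set NTg replicate 1 with TCL1 Tg replicates 1, 2 and 4 against the other 4 arrays, an exchange of 1 array per group that leaves 6 of the 8 with their genotype. For PTPROt Tg against NTg, double Tg against TCL1 Tg and the interaction, the real count was 0, which any split reaches (35 of 35, 35 of 35 and 100 of 100), so these counts say nothing on a random grouping. The highest other counts were 5, 236 and 5. The split with 236 genes set TCL1 Tg replicates 1 and 3 with double Tg replicates 3 and 4 against the rest. It was picked as the highest after the counts were seen, and whether it reflects a structure of the samples was not tested.

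Single arrays far from the other 3 of their group were found for 8 of 120 list means (6 by chance, at 1 in 20) and 28 of 728 gene values (36.4 by chance). Among list means these were NTg replicate 1 for follicular markers (10.7), DNA replication (8.08) and neutrophil markers (6.02), NTg replicate 2 for heat shock genes (8.76), PTPROt Tg replicate 4 for B cell receptor signalling (10.4), PTPROt Tg replicate 3 for macrophage markers (9.22), and TCL1 Tg replicate 3 for NF-kB targets (8.83) and heat shock genes (8.78). In NTg arrays, replicate 1 stood apart for Pdia4 (11.3) and Tyms (7.72), replicate 2 for Sesn1 (10.9) and replicate 3 for Apobec3 (8.27) and Cd72 (12.4). In PTPROt Tg arrays, replicate 3 stood apart for Epor (7.18), Lef1 (7.82) and Plscr1 (8.89), and replicate 4 for Eno3 (7.66), Pa2g4 (9.44) and Pdcd1lg2 (6.94). In TCL1 Tg arrays, replicate 1 stood apart for Pdia4 (12.4) and Zbtb32 (10.4), replicate 3 for Fcer2a (10.8), Fcgr2b (9.84) and Nme7 (7.40), and replicate 4 for Cenpa (9.52). In double Tg arrays, replicate 1 stood apart for Ahnak (8.89), Cd5 (7.87), Clec9a (5.42) and Nme7 (9.57), replicate 2 for Il2rb (7.48), replicate 3 for Ier5 (8.66) and Il12a (7.05), and replicate 4 for Aldoa (11.4), Cd27 (7.60), Fasl (5.35) and Klra8 (3.72).

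The PTPROt difference itself differed between arrays with and without TCL1 for 12 lists by camera at the preset correlation: B-1 markers (0.543), germinal centre markers (-0.571), plasma cell genes (-0.343), G2/M genes (-0.51), DNA replication genes (-0.264), p53 targets (-0.109), FOXO targets (-0.154), interferon-stimulated genes (-0.217), MYC targets (0.0799), T cell markers (-0.299), NK cell markers (-0.383) and macrophage markers (0.131). With an estimated correlation 0 of them passed, and the smallest adjusted p was 0.238, for plasma cell genes. Leaving out 1 array ended the call of 4 of these lists. They were interferon-stimulated genes without TCL1 Tg replicate 4 (-0.0876), NK cell markers without TCL1 Tg replicate 3 (-0.122) and MYC targets without NTg replicate 1, PTPROt Tg replicate 4 or double Tg replicate 4 (0.0335, 0.0411 and 0.045). Macrophage markers did not pass without NTg replicate 1, PTPROt Tg replicate 4, TCL1 Tg replicate 2 or double Tg replicates 2 or 3 (0.0384, 0.0888, 0.058, 0.0191 and 0.106). Other values moved by over 1.5 times and still passed. Without NTg replicate 1, G2/M, DNA replication and FOXO means were -0.781, -0.437 and -0.102. Without TCL1 Tg replicate 4, G2/M and DNA replication means were -0.336 and -0.15, and without double Tg replicate 3 the DNA replication mean was -0.152. The germinal centre mean was -0.37 without TCL1 Tg replicate 2 and the T cell mean -0.145 without TCL1 Tg replicate 3. Interferon-stimulated genes were at -0.123 and -0.119 without NTg replicate 3 and PTPROt Tg replicate 3, and MYC targets at 0.141 without NTg replicate 3. Macrophage markers were at 0.223, 0.226 and 0.21 without NTg replicate 4, PTPROt Tg replicate 3 and double Tg replicate 1.

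Outside the genes tested, 3 of 12146 unnamed probe sets passed in TCL1 Tg against NTg (10340771 at 0.85, 10343841 at 0.57 and 10408220 at -1.03), 41 in double Tg against NTg (27 higher) and 38 in double Tg against PTPROt Tg (30 higher). Of 1621 probe sets with several symbols, 393 passed in TCL1 Tg against NTg (105 higher, 288 lower), 416 in double Tg against NTg (129 higher, 287 lower) and 374 in double Tg against PTPROt Tg (123 higher, 251 lower). In PTPROt Tg against NTg 3 passed, all with the same symbols (10418185 at 0.55, 10418198 at 0.56 and 10418210 at 0.56, adjusted p = 0.0218 from limma).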

How the results depend on the processing

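The erythroid covariate, the omission of the highest-erythroid arrays, the omission of genes near H2-Ea, the permutation of list means and the shared probe set covariate were chosen after the data were seen. With array weights the counts of changed genes were 2094 in TCL1 Tg against NTg, 1989 in double Tg against NTg and 2919 in double Tg against PTPROt Tg, and with a 1.5-fold minimum, which can only remove genes, 349, 315 and 408. Fits of only the compared groups gave 140 and 416 genes in TCL1 Tg and double Tg against NTg, and 1107 in double Tg against PTPROt Tg with as many arrays. With the shared probe set covariate it was 88, 112 and 108 genes, and 16 lists in double Tg against PTPROt Tg. The erythroid covariate gave 2126 genes in double Tg against NTg, and without the highest-erythroid arrays (NTg replicate 1, PTPROt Tg replicate 3, TCL1 Tg replicate 4 and double Tg replicate 4) there were 471 there and 457 in double Tg against PTPROt Tg. Beyond the removal of genes by the 1.5-fold minimum, the cause was not tested. Apart from the replicate block, every other setting with all arrays gave counts within 1.5 times the main one in these comparisons (780 to 1284, 862 to 1191 and 1059 to 1382), with 0 genes in the other comparisons. Similar counts did not mean the same genes. Quantile normalization kept 673 of the 1005, 734 of the 986 and 951 of the 1227 main calls. Median centring kept 755, 814 and 1004 of them, and the average of probe sets 971, 962 and 1200. The direction of the calls varied too. Higher calls were 619 of 1005, 617 of 986 and 707 of 1227 in these comparisons, 41 of 88, 42 of 112 and 51 of 108 with the shared probe set covariate, and 1109 of 2094, 1068 of 1989 and 1374 of 2919 with array weights. They were 729 of 951, 862 of 1191 and 831 of 1273 with the filter on dim genes and 472 of 780, 626 of 871 and 733 of 1059 with median centring. In double Tg against NTg the erythroid covariate gave 1084 of 2126. The cause was not tested.

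With an estimated correlation 0 lists passed in any comparison, and by exact permutation of list means, adjusted over 30 lists, 0 passed in any of the 5 comparisons between groups. With p no lower than 0.0286, a list could pass this permutation only if many others reached that value too, so its count says little. The relation of the PTPROt difference to the TCL1 difference was 0.00753 with the TCL1 Tg arrays split, against -0.302, because shared arrays give a negative value by construction, and -0.26 with the filter on dim genes.

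Leaving out 1 array at a time gave 163 genes (without NTg replicate 3) to 1972 (without NTg replicate 1) in TCL1 Tg against NTg and 251 to 1773 (the same arrays) in double Tg against NTg. It gave 392 (without double Tg replicate 4) to 1502 (without PTPROt Tg replicate 3) in double Tg against PTPROt Tg. The range was 0 to 5 genes (without NTg replicate 3) in PTPROt Tg against NTg, 0 to 1 (without double Tg replicate 1) in double Tg against TCL1 Tg and 0 to 4 (without NTg replicate 3) in the interaction. List counts ranged from 13 to 15, 4 to 8 (8 without NTg replicate 1, 7 without replicate 2), 11 to 15, 9 to 12, 8 to 12 and 10 to 14, in the order TCL1 Tg, PTPROt Tg, double Tg against TCL1 Tg, against NTg, against PTPROt Tg and interaction. The erythroid list changed sign to 0.0641 in PTPROt Tg against NTg without NTg replicate 1 and to 0.0628 in double Tg against TCL1 Tg without TCL1 Tg replicate 4, and the interferon-stimulated list to -0.016 in TCL1 Tg against NTg without TCL1 Tg replicate 4. The cause was not tested.

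Of 210 calls of named genes, 198 held with quantile normalization, 208 of 208 with the filter on dim genes, and 98 in every omission of an array, while 112 were lost in at least 1 and 0 changed sign. Of 149 results not past the threshold, 9 passed with quantile normalization and 14 of 123 with the filter. Of 64 list calls, 54 held with the filter, 57 of 62 with the erythroid covariate, 51 without the highest-erythroid arrays and 43 in every omission. In TCL1 Tg against NTg the filter ended 4 of 14 list calls, the most of any comparison.

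The replicate numbers of the labels did not pair the arrays: 7 of 24 pairs with the same number deviated together (r over 0.1), and 3 of 16 arrays correlated best with their own number. With the replicate block 725, 712 and 925 genes passed in TCL1 Tg against NTg, double Tg against NTg and double Tg against PTPROt Tg and 0 in the other comparisons. Of the calls of named genes 184 held and 26 were lost, and of the list calls 63 held.

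Taking log2 of the value + 1 was not run because the values were already on the log2 scale. Signal over background limits the dim genes: changes there are compressed, and no detection calls were used to set a floor.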

Other observations

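The tests of the list relations and of neighbouring genes, and the genes named here other than H2-Ea, Neto2, Dnah8, Msh5, Apobec3 and Nme7, were chosen after their values had been seen. Among the 8 arrays with the TCL1 transgene, the B-1 and germinal centre list means went in opposite directions (Pearson r = -0.81, permutation p = 0.0189, adjusted 0.0378; Spearman rho = -0.738, permutation p = 0.0458, adjusted 0.0917). Without the 2 farthest arrays r was -0.757, and with group means removed it was -0.777. B-1 and G2/M means were also opposed (r = -0.786, permutation p = 0.0167, adjusted 0.0378; rho = -0.929, permutation p = 0.00223, adjusted 0.0134; r = -0.836 without the 2 farthest). Germinal centre and G2/M means, each taken without the 1 gene that their lists share, went together (r = 0.88, permutation p = 0.00233, adjusted 0.014; rho = 0.905, permutation p = 0.00456, adjusted 0.0137; r = 0.734 without the 2 farthest). In all, 6 relations were computed, and the 3 with plasma cell genes did not pass. Animals with TCL1 may differ in how far B-1-like or germinal centre-like, dividing B cells make up the sample, a hypothesis that rests on the same arrays.

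A gap of at least 1 on the log2 scale between 2 levels, with at least 2 arrays on each, was found for 20 of 19938 genes. Of these, 4 followed the TCL1 transgene (H2-Ea, Neto2, Dnah8 and Msh5) and 16 did not. Apobec3 (means 8.12 and 11.4) and D730005E14Rik (5.85 and 9.53) were low in the 4 PTPROt Tg arrays and NTg replicate 3. The TRIM family genes Trim12a (4.94 and 9.92) and Trim30d (4.93 and 8.08) and Gm1966 (7.91 and 9.95) were low in 2 PTPROt Tg arrays, and the amino acid transporter gene Slc1a5 (8.76 and 10.2) in 3. Nme7 (mean 7.69 on the lower level) was low in TCL1 Tg replicate 3 and 3 double Tg arrays.

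Of the 50 genes with the smallest p in PTPROt Tg against NTg, 5 pairs were neighbours in the gene order (0.618 pairs on average in random sets), among them Apobec3 with D730005E14Rik and Cbx7, and Lynx1 (-1.22) with Ly6d (-1.02). Chromosome segments that segregate between strains are a candidate source, but 6 of the 35 splits of the 8 arrays gave as many (highest other 6), and segregating segments could raise the number in any split, so the 5 pairs do not decide it.

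For Neto2, a changed region that takes in the genes around it is argued against by the 100 surrounding genes, of which 2 passed in both TCL1 comparisons, against a mean of 2.04 in shifted windows (permutation p = 0.587).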
